A study of Homo sapiens with 43 samples.

How the data were processed

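The 43 libraries are 39 of GM12878 and 4 of HepG2, in 22 groups taken from the sample titles. Per the labels' protocols, RNA was enriched for polyadenylated transcripts, made into strand-marked libraries and read as pairs. The deposited files hold RSEM expected counts (estimated counts per gene, not scaled for depth or length), per the file headers. The submitters' processing notes name STAR, RSEM and the genome build hg38, without versions, settings or an annotation release. Whether counting used the strand is not given in the sources used here, so overlapping and antisense genes are uncertain. Each file has 59526 identifiers, of which 58780 are Ensembl genes and 58207 matched a symbol of GENCODE 44. The other 746 are purely numeric or name spike-in sequences, hold 0 counts and were left out, as were all other deposited columns. Between 2.48% and 4.74% of the values per file are not whole, and all were rounded.

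Libraries of GM12878 held 12.9 to 22.9 M counts, and the depth of each is given at the start of the results. Counts of replicate libraries were compared by chi-square over genes with at least 20 counts in both together. The lowest chi-square per degree of freedom was 2.52, so no pair agreed within sampling noise and none was counted as 1 sample.

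Each experiment had its own fit in edgeR 4.0.16 (R 4.3.3): the panel with 15 libraries and 8 groups, the pretreatment experiment with 24 and 12, and HepG2 with 4 and 2. Genes were kept by filterByExpr with the groups, which left 15775, 15183 and 13349 genes. TMM factors lay between 0.956 and 1.06. The quasi-likelihood test was used with robust dispersion and no covariates. Residual degrees of freedom were 7, 12 and 2, and the common biological coefficients of variation 0.0417, 0.0490 and 0.0788. All groups of an experiment entered its fit to share 1 estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of that comparison, 2-sided. Standard errors were taken as the size of the log2 fold change over the square root of F. CPM values are scaled by TMM and given as mean ± SD of the libraries.

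The labels do not say which vehicle belongs to which panel stimulus, so each stimulus was set against the mean of the DMSO and PBS groups, and both groups against each other. Within pretreatment, IFNg and Dex were compared with vehicle in each arm and time, BRM014 with DMSO in the vehicle libraries, and the interactions of stimulus and BRM014 at each time. Dox has 1 library and got no test. Its log2 ratios are of CPM plus 1 to the mean of the 4 vehicle libraries, and list medians were placed among 10000 random lists matched on expression. The retained response is the least-squares slope through 0 of the fold changes in BRM014 on those in DMSO, over genes raised over 2-fold in the panel. The number of calls shared by comparisons was set beside n1 × n2 / N for independent lists, per direction, and no such pair shares libraries. Genes with 3 counts or fewer over a group are given as a ratio with a 95% counting interval, or with 0 counts as a bound at 3 counts.

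Gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over the lists of a comparison. Genes were named by a rule. For panel IFNg, panel Dex, BRM014 at 6 h, the 6 h interactions and HepG2 these are the 8 largest rises and 8 largest falls among called genes with at least 5 CPM in the higher group, every treated library beyond every control library (not asked of interactions) and a symbol. Other comparisons take 4 each way, and Dox the 10 highest and 10 lowest beyond all vehicle libraries. Up to 4 members with the smallest adjusted p per list, the targets SMARCA4 and SMARCA2, receptor genes, a short set of known response genes, and the 6 lowest and 6 highest interaction p among the 50 largest panel responses were added. Some genes that the rule covers are not reported here. Where the text names a gene outside the rule it says so, and list members named in brackets beside counts of 5 or fewer were also chosen after their values were seen.

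The alternatives tried were DESeq2 size factors in edgeR, DESeq2 1.42.0 with its Wald test, no filter, the replicate number as a block, only the compared groups in the fit, each library left out, and DMSO or PBS alone as control. For the retained response a list from the DMSO arm and the 50 largest responses were tried, and for Dox a pseudocount of 0.1 CPM. A per-library offset on GC content and a crossed block in HepG2 were added after seeing the data. The pipeline was tested on simulated data with known folds of 1.5, 2 and 4. In the panel it recovered 72.9%, 87.1% and 100% of changed genes, for BRM014 at 6 h 77.1%, 93.4% and 98.6%, for the Dex interaction 53.8%, 73.8% and 95.7%, and in HepG2 58.1%, 86.6% and 95.7%. False calls were 15 of 188, 1 of 180, 9 of 159 and 21 of 182, above 5% in all but the BRM014 case. DESeq2 gave 1 of 140 in the HepG2 simulation. A retained slope of 0.5 came back as 0.495, and a GC trend that gave 6755 false calls gave 4 after the offset.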

Results

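RNA from 43 libraries of human cell lines, falling into 22 groups, was measured by sequencing of polyadenylated RNA. GM12878, a lymphoblastoid line of B cells transformed by Epstein-Barr virus, gave 39 libraries, and HepG2, a hepatocellular carcinoma line, gave 4. In the first GM12878 experiment, called the panel here, cells were exposed for 6 h to 1 of 6 stimuli or to a vehicle (DMSO or PBS). Each panel group had 2 libraries except doxorubicin (Dox, 500 nM), which had 1. The other stimuli were tumour necrosis factor alpha (TNF, 25 ng/mL), lipopolysaccharide (LPS, 10 ng/mL), interleukin 2 (IL2, 50 U/mL), interferon gamma (IFNg, 100 ng/mL) and dexamethasone (Dex, 500 nM). In the second GM12878 experiment, cells received DMSO or 10 µM BRM014 for 30 min before vehicle, IFNg or Dex for 1 h or 6 h, with 2 libraries in each of 12 groups. BRM014 inhibits SMARCA4 and SMARCA2, the ATPases of the BAF chromatin remodelling complexes. HepG2 cells received DMSO or 10 µM BRM014 for 24 h, with 2 libraries each.

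The deposited expected counts summed, in M for replicates 1 and 2 of each panel group, to DMSO 21.97 and 19.98, PBS 14.2 and 22.9, TNF 17.3 and 20.1, LPS 18.04 and 17.8, IL2 18.1 and 19.1, IFNg 16.6 and 16.7, Dex 15.7 and 20.99, with 20.2 for the Dox library. In the pretreatment experiment cells given DMSO for 1 h had 16.5 and 18.1 M with vehicle, 20.9 and 16.6 with IFNg and 16.2 and 17.6 with Dex. At 6 h they had 15.3 and 22.3 M with vehicle, 12.9 and 17.3 with IFNg and 17.8 and 13.8 with Dex. With BRM014 the 1 h values were 15.8 and 17.8 M with vehicle, 15.5 and 17.9 with IFNg and 15999205 counts and 18.4 with Dex. The 6 h values were 14.5 and 16.8 M with vehicle, 16.1 and 14.6 with IFNg and 15.5 and 17.3 with Dex. HepG2 libraries held 9.79 and 17.02 M with DMSO and 19.9 and 3.06 M with BRM014, so that BRM014 replicate 2 was the shallowest library of the series. The labels do not say that replicates were separate cultures, and p-values therefore measure only the spread between these samples, which may be technical. Fold changes below are log2 values ± SE from edgeR, and positions are on hg38 (GENCODE 44).

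The panel comparisons ask how GM12878 cells responded to each stimulus at 6 h. IFNg, which signals through its receptor and JAK kinases, was followed by higher levels of 1122 genes and lower levels of 750 of 15775 tested, of which 130 and 22 changed by over 2-fold (n = 2 IFNg and 4 vehicle libraries). The chemokine gene CXCL9 (ENSG00000138755.5, chromosome 4, 76001275 to 76007509) rose by 5.35 ± 0.070, from 7.38 ± 1.36 CPM (SD, n = 2) with DMSO and 6.91 ± 1.10 with PBS to 289.7 ± 0.634 with IFNg. HAPLN3, a gene of a hyaluronan link protein (ENSG00000140511.11, chromosome 15, 88877294 to 88895597), rose by 5.70 ± 0.12. The chemokine gene CXCL10 rose by 4.16 ± 0.092, UBD, which encodes a ubiquitin-like modifier, by 3.48 ± 0.061, and HGF, a growth factor gene, by 3.09 ± 0.21. The guanylate-binding protein genes GBP5, GBP4 and GBP1 rose by 4.29 ± 0.084, 3.91 ± 0.045 and 3.27 ± 0.050. These values are uncertain to the extent that near-identical family members share reads. The transcription factor gene IRF1 (ENSG00000125347.13, chromosome 5, 132440440 to 132508719) rose by 2.53 ± 0.043 (adjusted p = 7.29e-31), and SOCS1, an inhibitor of JAK signalling, by 1.83 ± 0.082. Among genes that fell were CD180, a Toll-like receptor homologue of B cells (-0.78 ± 0.092), LYPD6B (-0.81 ± 0.15) and PIK3IP1 (-0.74 ± 0.14).

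Camera p-values here and below are those with an estimated correlation. The gene lists share some members, so calls of different lists are not separate evidence. TAP1 and NLRC5, for example, are both IFNg targets and MHC class I genes. Of the lists fixed before the data were examined, 42 of 43 measured IFNg targets rose (42 up adjusted over the list alone; median 1.42; camera adjusted p = 1.59e-08). Among type I interferon-stimulated genes 30 of 32 rose (31 up adjusted over the list alone; camera adjusted p = 0.00539), including STAT2 by 1.24 ± 0.038 and EPSTI1 by 1.27 ± 0.056. MHC class I presentation genes rose in 15 of 19 cases (17 up adjusted over the list alone; camera adjusted p = 4.63e-04), with 1.89 ± 0.040 for the peptide transporter gene TAP1 and 1.54 ± 0.040 for NLRC5, the class I transactivator. Of 18 MHC class II presentation genes 4 rose (4 up adjusted over the list alone): CTSS, CIITA and IFI30, with 0.45 ± 0.049, 0.26 ± 0.038 and 0.21 ± 0.041, and RFX5. The call of RFX5 was lost without DMSO replicate 1, IFNg replicate 1 or IFNg replicate 2 (adjusted p = 0.0654, 0.174 and 0.0796). NF-kB and inflammatory targets rose in 21 and fell in 3 (CCL17, IL1B and LTB) of 38 cases (23 up and 4 down adjusted over the list alone; camera adjusted p = 4.63e-04). The adhesion gene ICAM1 rose by 0.76 ± 0.038 and TNF by 0.55 ± 0.043. B cell identity genes fell in 14 and rose in 5 (PAX5, IRF8, LYN, CD40 and CD72) of 37 cases (6 up and 17 down adjusted over the list alone; camera adjusted p = 0.019). The inhibitory receptor gene CD22 had -0.48 ± 0.043, the kinase gene BLK -0.41 ± 0.037 and the transcription factor gene IRF8 0.90 ± 0.036. The call of this list with the preset correlation was lost against DMSO alone (adjusted p = 0.0573). The 26 G2 and M phase genes had a median of -0.035, and the list was not called. The total of 1872 called genes became 1226 with DESeq2, 1218 without IFNg replicate 1 and 1060 without IFNg replicate 2.

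Dex, a synthetic agonist of the glucocorticoid receptor, changed more genes than the other 4 tested stimuli of the panel: 2052 rose and 2000 fell, 341 and 174 of them by over 2-fold (n = 2 and 4). TSC22D3, which encodes the anti-inflammatory factor GILZ (ENSG00000157514.16, chromosome X, 107713221 to 107777342), rose by 4.30 ± 0.046, to 482 ± 7.21 CPM (SD, n = 2) from 22.9 ± 1.12 with DMSO and 26.1 ± 0.0945 with PBS. OGFRL1 rose by 4.80 ± 0.090, VSTM2L by 4.75 ± 0.17, the sodium-proton exchanger gene SLC9A2 by 4.58 ± 0.33, and LGR4, a receptor gene of the Wnt pathway, by 3.99 ± 0.28. FKBP5, a co-chaperone gene of the receptor itself (ENSG00000096060.14, chromosome 6, 35573585 to 35728583), rose by 2.81 ± 0.037 (adjusted p = 7.61e-34), the mTOR regulator gene DDIT4 by 2.49 ± 0.044 and the clock gene PER1 by 1.22 ± 0.058. The receptor gene NR3C1 (ENSG00000113580.14, chromosome 5, 143277931 to 143435512) changed by -0.60 ± 0.045. Among genes that fell were IL1B, which encodes interleukin 1 beta (-2.86 ± 0.23), the immune receptor gene TIGIT (-2.00 ± 0.20), GBP4 (-1.62 ± 0.075) and the chemokine receptor gene CXCR5 (-1.52 ± 0.15).

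Under Dex, 26 of 33 glucocorticoid-induced genes rose and 2 (SGK1 and GADD45A) fell (27 up and 2 down adjusted over the list alone; median 0.92; camera adjusted p = 5.33e-07). NF-kB and inflammatory targets fell in 25 and rose in 6 of 38 cases (7 up and 26 down adjusted over the list alone; camera adjusted p = 6.62e-04). The lymphotoxin genes LTA and LTB changed by -1.27 ± 0.051 and -1.19 ± 0.060, while BIRC3 and CFLAR, which encode inhibitors of apoptosis, rose by 0.68 ± 0.038 and 0.92 ± 0.035. IFNg targets fell in 25 and rose in 6 of 43 cases (6 up and 29 down adjusted over the list alone; camera adjusted p = 0.00411). Their median was -0.36, or -0.31 with members at 0 counts set to their bound. MHC class II genes fell in 14 of 18 cases (14 down adjusted over the list alone; camera adjusted p = 0.0203), with -0.53 ± 0.040 for the class II transactivator CIITA. B cell identity genes fell in 24 and rose in 9 of 37 (9 up and 25 down adjusted over the list alone; camera adjusted p = 6.62e-04). CD22 had -0.91 ± 0.044, PAX5 -0.74 ± 0.042 and IRF4 0.62 ± 0.034. Among 12 plasma cell genes 3 (PRDM1, ELL2 and TENT5C) rose and 2 (JCHAIN and SEC11C) fell (3 up and 2 down adjusted over the list alone). PRDM1, a regulator of plasma cell formation, rose by 1.00 ± 0.063, and SEC11C lost its call without Dex replicate 1 (adjusted p = 0.109). Immediate-early genes went both ways, 9 up and 7 down of 29 (10 up and 8 down adjusted over the list alone), with 1.15 ± 0.048 for KLF6 and -1.08 ± 0.081 for EGR2. Of 26 G2 and M phase genes CCNB1 and PLK1 fell and BUB1 rose (2 down adjusted over the list alone), with -0.29 ± 0.057, -0.23 ± 0.050 and 0.15 ± 0.054. BUB1 lost its call without DMSO replicate 1, PBS replicate 1, Dex replicate 1 or Dex replicate 2 (adjusted p = 0.0892, 0.093, 0.0517 and 0.28). DESeq2 called 2649 genes in place of 4052.

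**Figure D1:**
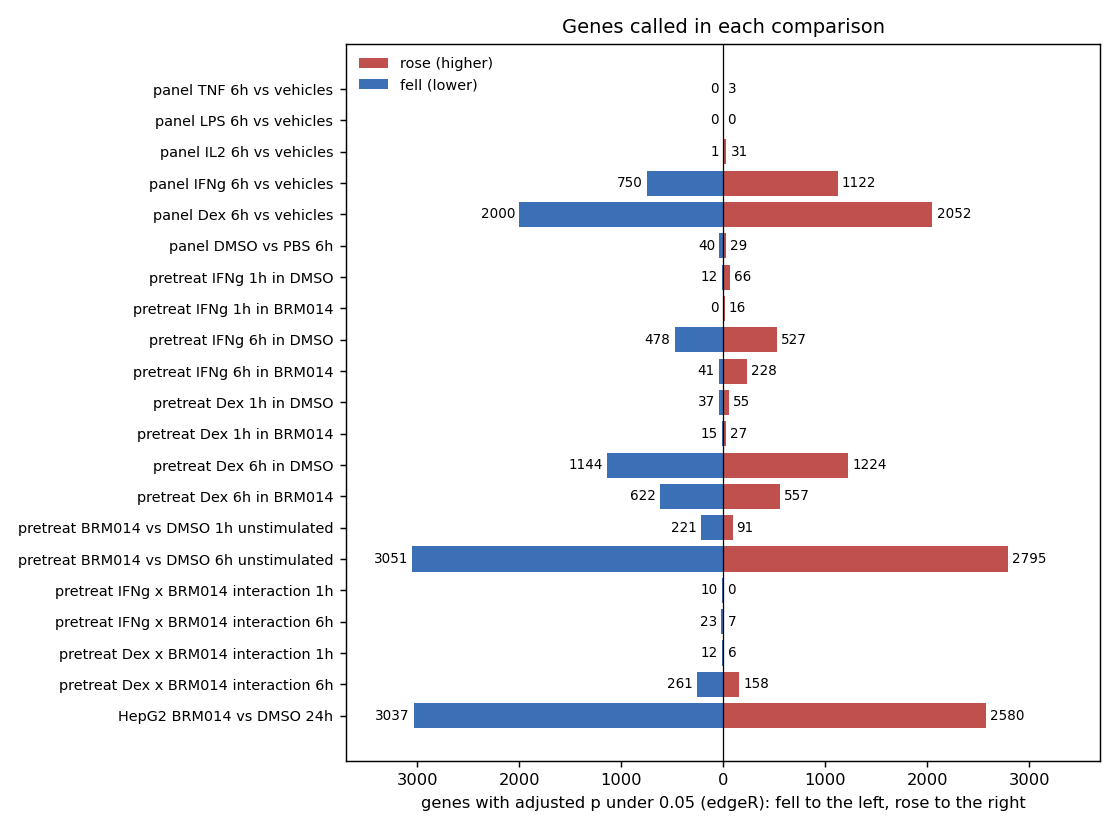
Number of genes called at a Benjamini-Hochberg adjusted p under 0.05 in each of the 21 tested comparisons, with genes that fell drawn to the left of 0 and genes that rose to the right. The longest bars belong to BRM014 in GM12878 at 6 h, BRM014 in HepG2 at 24 h and Dex in the panel, and the bar of LPS is empty.

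TNF, which activates NF-kB through its receptors, was followed by small changes. PIM2, a kinase gene, rose by 0.22 ± 0.038 and the NF-kB target BIRC3 by 0.21 ± 0.039 (adjusted p = 0.00984 and 0.022; n = 2 and 4). The third called gene, ENSG00000173366, has no symbol in the tables used, falls outside the naming rule and was chosen after its values were seen. It rose by 0.71 ± 0.11 (adjusted p = 0.0035). The known targets NFKBIA and TNFAIP3 did not pass, with 0.11 ± 0.039 and 0.14 ± 0.036. Of 38 measured NF-kB and inflammatory targets 1 rose (10 up adjusted over the list alone; median 0.053; camera adjusted p = 4.67e-04). No gene of the other lists passed over all genes in edgeR, and DESeq2 called 2 genes. An unadjusted p under 0.05 was found for 792 genes, about the 5% of 15775 that chance alone would give. The medians were 0.077 for 43 IFNg targets (2 up adjusted over the list alone; camera adjusted p = 0.00984), 0.11 for 32 type I interferon-stimulated genes (adjusted p = 0.218 with an estimated correlation) and -0.0083 for 37 B cell identity genes. The call of the type I list with the preset correlation was lost without TNF replicate 2 (adjusted p = 0.0847). The receptor genes TNFRSF1A and TNFRSF1B stood at 16.7 ± 2.64 and 96.6 ± 4.65 CPM (SD, n = 4) in the vehicle libraries. Call totals moved to 1 without DMSO replicate 1, 8 and 8 without PBS replicates 1 and 2, 1 and 0 without TNF replicates 1 and 2. They were 38 against DMSO alone, 0 against PBS alone, 22 with no filter and 16 with an offset on GC content. PIM2 and BIRC3 lost their calls without TNF replicate 1 (adjusted p = 0.256 and 0.598), TNF replicate 2 (adjusted p = 0.949 and 0.937) or DMSO replicate 1 (adjusted p = 0.177 and 0.173). BIRC3 also lost its call without DMSO replicate 2 (adjusted p = 0.134).

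LPS, a bacterial ligand of TLR4, gave 0 called genes in edgeR and 0 in DESeq2. An unadjusted p under 0.05 was found for 776 genes, about the 5% of 15775 that chance alone would give. NFKBIA and TNFAIP3 had fold changes of 0.042 ± 0.039 and 0.088 ± 0.036. CD14 and TLR4, which encode the LPS co-receptor and receptor, stood at 0.200 ± 0.112 and 0.103 ± 0.0787 CPM (SD, n = 4) in the vehicle libraries, the latter with 0 to 4 counts per library. LY96, the gene of the TLR4 partner MD-2, stood at 6.22 ± 0.337 CPM. Although no member of the 4 lists passed over all genes, type I interferon-stimulated genes had a median of 0.16 with 6 of 32 higher adjusted over the list alone (camera adjusted p = 0.0301), among them XAF1 at 0.28 ± 0.064 and USP18 at 0.29 ± 0.076. The medians were 0.052 for NF-kB and inflammatory targets (camera adjusted p = 0.00561), 0.076 for IFNg targets (camera adjusted p = 0.00768) and 0.035 for B cell identity genes (camera adjusted p = 0.0301). The same vehicle libraries are the control of TNF, where IFNg targets had a median of 0.077. The small list shifts with TNF and LPS are therefore not independent. A shift in the shared vehicle libraries cannot be told apart from a response to either stimulus. The number of called genes was 3 and 5 without PBS replicates 1 and 2, 3 and 1 without LPS replicates 1 and 2, and 35 against DMSO alone. It was 20 with no filter, 2 with only the compared groups in the fit and 1 with an offset on GC content. The B cell list lost its call with the preset correlation without PBS replicate 2 or LPS replicate 2 and against PBS alone (adjusted p = 0.0645, 0.291 and 0.835), as did the NF-kB list against PBS alone (adjusted p = 0.057).

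IL2 raised 31 genes. IL2RA, which encodes the alpha chain of its receptor (ENSG00000134460.17, chromosome 10, 6010689 to 6062370), rose by 1.35 ± 0.078, from 14.6 ± 1.08 CPM (SD, n = 4) to 37.3 ± 1.95 (SD, n = 2; adjusted p = 9.43e-14). CISH, a feedback inhibitor of STAT5 signalling (ENSG00000114737.15, chromosome 3, 50606489 to 50611774), rose by 1.31 ± 0.12 (adjusted p = 2.58e-08). The chemokine gene CCL17 and the lymphotoxin gene LTA rose by 0.66 ± 0.065 and 0.64 ± 0.044. Of 20 IL2 and STAT5 targets 6 rose (11 up adjusted over the list alone; median 0.26; camera adjusted p = 7.79e-06). NF-kB and inflammatory targets rose in 7 of 38 cases (22 up adjusted over the list alone; camera adjusted p = 3.75e-06). LTA is a member of both of these lists. ICAM1, which is also in the NF-kB list, was the 1 IFNg target of 43 that rose (0.21 ± 0.039). In the IFNg target list 4 were up adjusted over the list alone (camera adjusted p = 0.00187). The call of ICAM1 was lost without IL2 replicate 1 or 2 and against PBS alone. IL2 was set against the same vehicle libraries as TNF and LPS, so its list calls are not independent of theirs. The shift of the IFNg target list, with 1 called gene, cannot be told apart from a shift in those libraries. The single gene that fell, ENSG00000277067, has no symbol and was chosen after its values were seen. It had 0 counts over both IL2 libraries against 38 over the vehicle libraries, at least 5.96-fold lower by the floor of 3 counts over a group. The total of 32 became 56 without PBS replicate 1, 12 and 11 without IL2 replicates 1 and 2, 98 against DMSO alone, 10 against PBS alone, 73 with no filter and 67 with an offset on GC content.

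Because the labels do not tie a vehicle to each stimulus, both vehicles were compared with each other. With DMSO, 29 genes were higher and 40 lower than with PBS (n = 2 each). SLC30A1, a zinc exporter gene (ENSG00000170385.9, chromosome 1, 211571568 to 211579161), was higher by 0.63 ± 0.10 (adjusted p = 0.00205) and kept its call under each library left out. KLHL28 was higher by 0.70 ± 0.12, and the growth factor gene PDGFA and the kinase gene IKBKE lower, with -0.72 ± 0.14 and -0.53 ± 0.083. These 3 lost their calls without DMSO replicate 1 (adjusted p = 0.0897, 0.287 and 0.0897), and PDGFA also without replicate 2 of DMSO or PBS (adjusted p = 0.125 and 0.0681). PEDS1-UBE2V1, a readthrough transcript that shares reads with its component genes and is uncertain, changed by -1.59 ± 0.23 and lost its call without DMSO replicate 1 (adjusted p = 0.111). The total of 69 became 2 and 18 without DMSO replicates 1 and 2, 13 and 410 without PBS replicates 1 and 2, 11 with the vehicle libraries alone in the fit and 132 with no filter.

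Dox, a DNA-intercalating inhibitor of topoisomerase II, was given to 1 library, so its values have no replicate check and no test. CDKN1A, the p53 target that encodes the cell cycle inhibitor p21 (ENSG00000124762.13, chromosome 6, 36676460 to 36687337), was at 873 CPM against 288 ± 12.9 (SD, n = 4) in the vehicle libraries, and MDM2, the p53 ubiquitin ligase gene, at 328 against 129 ± 16.4. Their log2 ratios (pseudocount 1 CPM) were 1.60 and 1.35. The highest ratios included 2.14 for FOSL1, 1.98 for PHLDA3, 1.93 for SESN1, 1.90 for EDA2R, 1.85 for TIGAR and 1.74 for BBC3. Of the genes named here all but FOSL1 belong to the p53 list. These genes are a selection from the highest ratios and do not show what share of the highest ratios belongs to that list. All 34 measured p53 targets lay above every vehicle library, with a median ratio of 1.22 at percentile 100 of 10000 random lists matched on expression. KIF20A, PLK1 and CENPA, which act in mitosis, had ratios of -1.54, -1.45 and -1.39. Of the G2 and M phase genes 25 of 26 (all but NUSAP1) lay below every vehicle library (median -0.67, percentile 0). Replication-dependent histone genes had a median of -0.065 (percentile 23.8) and immediate-early genes one of 0.063 (percentile 94.2). The histone values are uncertain, as near-identical copies and because the libraries were enriched for polyadenylated RNA. Both list medians depend on the setting: against DMSO alone histone and immediate-early genes had 0.018 (percentile 68.9) and 0.0952 (percentile 99.1), and with a pseudocount of 0.1 CPM -0.049 (percentile 38.5) and 0.11 (percentile 99.2). The ratios of MYC, the adhesion gene VCAM1 and the cyclin gene CCNB1 were -1.13, -1.20 and -1.08.

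Whether a response recurred in separate libraries was asked by setting the panel beside the DMSO arm of the pretreatment experiment at 6 h, which share no libraries. For IFNg, 457 genes rose and 303 fell in both, where independent lists would share 39.0 and 23.8, and 0 were called in opposite directions. For Dex, 1036 rose and 976 fell in both, against 164 and 151, with 0 in opposite directions. Across genes called in either experiment, which are not independent replicates, Pearson's r of the fold changes was 0.82 for IFNg and 0.86 for Dex. IRF1 rose by 2.53 and 2.40, and FKBP5 by 2.81 and 2.74.

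What the BAF inhibitor did without a stimulus was asked with the vehicle groups of the pretreatment experiment (n = 2 each). After 1 h plus the 30 min of pretreatment, 221 genes fell and 91 rose. DEPP1 (ENSG00000165507.8, chromosome 10, 44970981 to 44978809) fell (-2.54 ± 0.23). The stress-response gene IER3, the B cell gene CD180 and LAX1, an adaptor of antigen receptor signalling, had fold changes of -1.96 ± 0.12, -1.73 ± 0.15 and -1.55 ± 0.13. The nuclear receptor gene NR4A2 and the kinase gene PIM1 rose by 1.92 ± 0.20 and 1.17 ± 0.10. At 6 h 3051 genes fell and 2795 rose, 895 and 267 by over 2-fold. The chemokine genes CCL4 and CCL3, which are uncertain as they have near-identical copies, fell (-3.95 ± 0.25 and -3.05 ± 0.12). So did DEPP1 (-3.88 ± 0.27), CD180 (ENSG00000134061.5, chromosome 5, 67179613 to 67196799; -3.85 ± 0.20), LAX1 (-3.77 ± 0.17), TLR9, which senses unmethylated DNA (-3.59 ± 0.59), and the adhesion gene CEACAM1 (-3.30 ± 0.26). ZMYM1 (ENSG00000197056.10, chromosome 1, 35032172 to 35115859) rose by 2.64 ± 0.25, AMN1 by 2.37 ± 0.23, the zinc finger gene ZNF341 by 2.02 ± 0.18 and PIM1 by 1.86 ± 0.10. Of the inhibitor's targets, SMARCA4 (ENSG00000127616.18, chromosome 19, 10960932 to 11079426) rose by 0.29 ± 0.052 and SMARCA2 (ENSG00000080503.23, chromosome 9, 1980290 to 2193624) changed by -0.44 ± 0.045 (adjusted p = 3.05e-05 and 3.17e-09). The 1 h total of 312 became 177 and 149 without DMSO and vehicle replicates 1 and 2. It became 198 and 203 without BRM014 and vehicle replicates 1 and 2.

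Interferon, NF-kB and B cell genes were lower under BRM014 at 6 h. Of 42 IFNg targets 35 fell (35 down adjusted over the list alone; camera adjusted p = 0.00664), with -1.36 ± 0.068 for CIITA and -1.02 ± 0.061 for IRF8. Type I interferon-stimulated genes fell in 30 and rose in 1 (IFIH1) of 32 cases (1 up and 31 down adjusted over the list alone; camera adjusted p = 2.74e-04), with -1.54 ± 0.053 for MX1 and -2.14 ± 0.079 for OAS1, both antiviral effectors. NF-kB and inflammatory targets fell in 30 and rose in 2 (BIRC3 and BCL3) of 38 (2 up and 32 down adjusted over the list alone; camera adjusted p = 0.0053), with -1.35 ± 0.055 for TRAF1. B cell identity genes fell in 32 and rose in 1 (BLNK) of 37 (1 up and 32 down adjusted over the list alone; camera adjusted p = 1.77e-04), with -1.78 ± 0.090 for the antigen receptor gene CD79B and -1.59 ± 0.056 for CD22. Immediate-early genes fell in 22 and rose in 1 (NR4A2) of 28 (1 up and 23 down adjusted over the list alone; camera adjusted p = 0.0139), with -3.03 ± 0.18 for EGR3 and -0.99 ± 0.070 for MYC. MHC class I genes fell in 16 of 19 (18 down adjusted over the list alone; adjusted p = 0.0861 with an estimated correlation), with -1.10 ± 0.074 for NLRC5. MHC class II genes fell in 5 (CIITA, HLA-DQB1, HLA-DMB, HLA-DOB and IFI30) and rose in 2 (CTSS and RFX5) of 18 (2 up and 5 down adjusted over the list alone). HLA genes share reads and are uncertain. Plasma cell genes gave 5 falls (PRDM1, SDC1, MZB1, TNFRSF17 and ELL2) and 1 rise (XBP1) of 12 (1 up and 6 down adjusted over the list alone; adjusted p = 0.0861 with an estimated correlation), with -1.34 ± 0.10 for PRDM1.

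Outside the immune lists, 6 rose and 14 fell of 33 glucocorticoid-induced genes (7 up and 15 down adjusted over the list alone; adjusted p = 0.137 with an estimated correlation), with -1.01 ± 0.050 for TXNIP. Among p53 targets 5 (SESN1, FDXR, XPC, ASCC3 and DRAM1) rose and 13 fell of 34 (6 up and 14 down adjusted over the list alone; adjusted p = 0.299 with an estimated correlation), with -1.39 ± 0.064 for CDKN1A. S phase genes rose in 14 of 22 cases (14 up adjusted over the list alone; adjusted p = 0.259 with an estimated correlation), with 0.70 ± 0.074 for E2F1 and 0.48 ± 0.058 for the helicase gene MCM6. Of G2 and M phase genes 4 (CDK1, KIF11, KIF23 and TTK) rose and 3 (BUB1B, KIF20A and HMMR) fell of 26 (4 up and 3 down adjusted over the list alone), and KIF23 lost its call without DMSO and vehicle replicate 1 or BRM014 and vehicle replicate 2 (adjusted p = 0.0526 and 0.0714). BAF subunit genes rose in 11 and fell in 3 (SMARCA2, SMARCB1 and SMARCC1) of 26 (11 up and 3 down adjusted over the list alone), with 0.75 ± 0.083 for BICRAL, -0.52 ± 0.046 for SMARCC1 and -0.40 ± 0.057 for SMARCB1. Cholesterol synthesis genes split, as 7 rose and 7 fell of 23 (7 up and 8 down adjusted over the list alone), with -0.51 ± 0.072 for INSIG1 and 0.30 ± 0.066 for SQLE. Among heat shock genes 4 (HSPA1B, HSPA8, BAG3 and HSPA4L) rose and 8 fell of 17 (5 up and 8 down adjusted over the list alone). Among stress and unfolded protein response genes 3 (ASNS, PSAT1 and XBP1) rose and 10 fell of 23 (3 up and 10 down adjusted over the list alone). Among histone genes, uncertain as near-identical copies in libraries enriched for polyadenylated RNA, 4 (H2AC11, H2BC5, H2BC12 and H3C10) rose of 12 (4 up adjusted over the list alone). Of these, H2AC11 lost its call without any 1 of the 4 libraries (adjusted p from 0.0553 to 0.233) and H2BC5 without BRM014 and vehicle replicate 2 (adjusted p = 0.0578). H2BC12 lost its call without DMSO and vehicle replicate 2 or BRM014 and vehicle replicate 1 (adjusted p = 0.458 and 0.131) and H3C10 without replicate 2 of either group (adjusted p = 0.0902 and 0.194). The 13 mitochondrially encoded transcripts had a median of -0.0077 and the 4 measured myeloid markers one of -0.25, without a call. Of 5 measured T and NK cell genes 3 fell, TRAC, PRF1 and NKG7 (4 down adjusted over the list alone). NKG7 lost its call without DMSO and vehicle replicate 1 or BRM014 and vehicle replicate 1 or 2 (adjusted p = 0.108, 0.0663 and 0.122). At 1 h the lists with the most calls were NF-kB and inflammatory targets, of which 2 (BIRC3 and RELA) rose and 11 fell of 38 (2 up and 17 down adjusted over the list alone; camera adjusted p = 0.043), and immediate-early genes, of which 7 rose and 7 fell of 28 (8 up and 11 down adjusted over the list alone). Of glucocorticoid-induced genes 5 (PER1, SGK1, BIRC3, ZFP36 and ZFP36L2) rose and 6 fell of 33 (8 up and 9 down adjusted over the list alone).

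**Figure D2:**
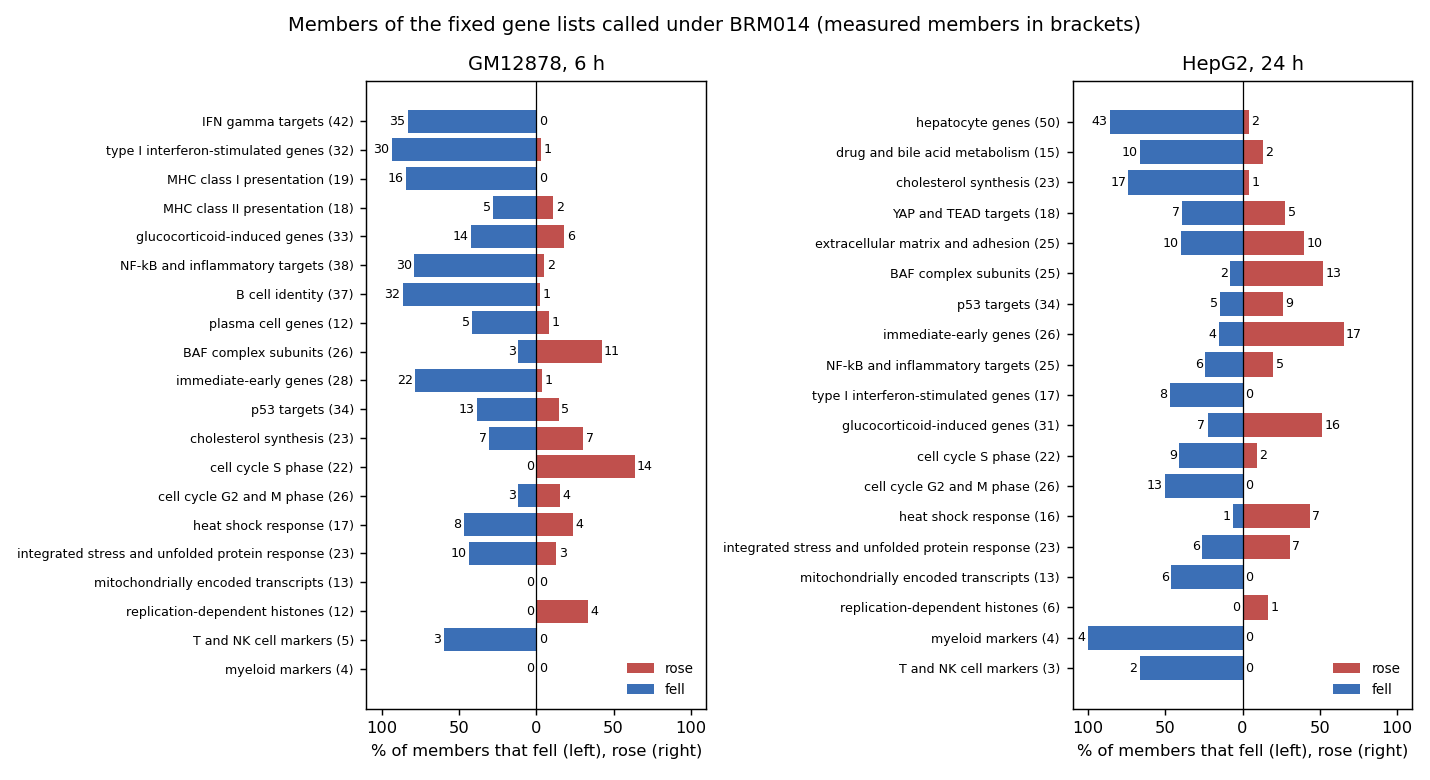
Percent of the measured members of each fixed list that rose (right of 0) or fell (left of 0) under BRM014, in GM12878 at 6 h without a stimulus and in HepG2 at 24 h, with the number of members beside each bar (n = 2 libraries per group). In GM12878 the bars of interferon, NF-kB and B cell genes lie almost wholly to the left, and in HepG2 those of hepatocyte and cholesterol genes do.

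The pretreatment experiment asks whether the IFNg response needs BAF activity. After 1 h in DMSO, 66 genes rose and 12 fell. IRF1 rose by 3.33 ± 0.19, SOCS3 by 3.05 ± 0.11, SOCS1 by 2.51 ± 0.14 and ICAM1 by 1.00 ± 0.078, and the repressor gene ID3 changed by -0.73 ± 0.084. After 1 h in BRM014, 16 genes rose and 0 fell in edgeR. An unadjusted p under 0.05 was found for 448 genes, fewer than the 5% of 15183 that chance alone would give. DESeq2 called 2 falls, as did edgeR with no filter, and 5 with only the compared groups in the fit. The repressor gene BCL6 rose by 3.94 ± 0.43, IRF1 by 3.46 ± 0.19, SOCS3 by 1.55 ± 0.11 and SOCS1 by 1.36 ± 0.14. IFNg targets rose in 14 of 42 cases in DMSO (17 up adjusted over the list alone; camera adjusted p = 5.44e-06) and 7 in BRM014 (9 up adjusted over the list alone; camera adjusted p = 0.002). At 6 h 527 genes rose and 478 fell in DMSO, and 228 and 41 in BRM014, of which 190 rose and 19 fell in both. HAPLN3 rose by 5.37 ± 0.28 and 4.10 ± 0.38, GBP4 by 3.73 ± 0.16 and 2.82 ± 0.18, and TAP1 by 1.76 ± 0.062 and 1.72 ± 0.062. In DMSO 39 IFNg targets rose (39 up adjusted over the list alone; camera adjusted p = 6.68e-08) and in BRM014 28 (34 up adjusted over the list alone; camera adjusted p = 4.85e-08). Type I interferon-stimulated genes rose in 27 (camera adjusted p = 2.55e-05) and 29 (camera adjusted p = 2.94e-07) of 32 cases and MHC class I genes in 13 (camera adjusted p = 6.78e-06) and 12 (camera adjusted p = 6.67e-07) of 19. B cell identity genes fell in 14 of 37 in DMSO (camera adjusted p = 0.0162). The totals became 50 and 50 (from 78, 1 h in DMSO) without DMSO and vehicle 1 h replicates 1 and 2, 10 (from 16, 1 h in BRM014) without BRM014 and IFNg 1 h replicate 1. At 6 h they became 663 (from 1005 in DMSO) without DMSO and vehicle 6 h replicate 2, and 170 (from 269 in BRM014) without BRM014 and vehicle 6 h replicate 1. With only the compared groups in the fit they were 128, 24, 349 and 470 in the same order, and IRF1 at 1 h in BRM014 lost its call (adjusted p = 1).

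Whether BRM014 altered the response itself was tested by the interaction of IFNg and BRM014. At 6 h 23 genes had a lower and 7 a higher IFNg response under BRM014 (adjusted p under 0.05; n = 2 in each of 4 groups). IFIT3, a type I interferon-stimulated gene, had a larger response (0.63 ± 0.10). Lower responses were those of UBD (-2.48 ± 0.26), the tryptophanyl-tRNA synthetase gene WARS1 (-1.30 ± 0.14), ZNF697 (-1.79 ± 0.23) and BPGM (-1.12 ± 0.16). UBD rose by 3.34 in DMSO and 0.86 in BRM014, and WARS1 by 2.20 and 0.90. SOCS1, with -1.03 ± 0.20, lost its call without DMSO and vehicle replicate 1 or 2, DMSO and IFNg replicate 1, BRM014 and vehicle replicate 1 or BRM014 and IFNg replicate 1 (adjusted p from 0.0746 to 0.298). At 1 h 10 genes had a lower and 0 a higher response in edgeR (442 genes at an unadjusted p under 0.05; DESeq2 called 0 higher), among the lower ones ZNF697 (-1.64 ± 0.23), SOCS3 (-1.50 ± 0.16) and the phosphodiesterase gene PDE4B (-1.20 ± 0.15).

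**Figure D3:**
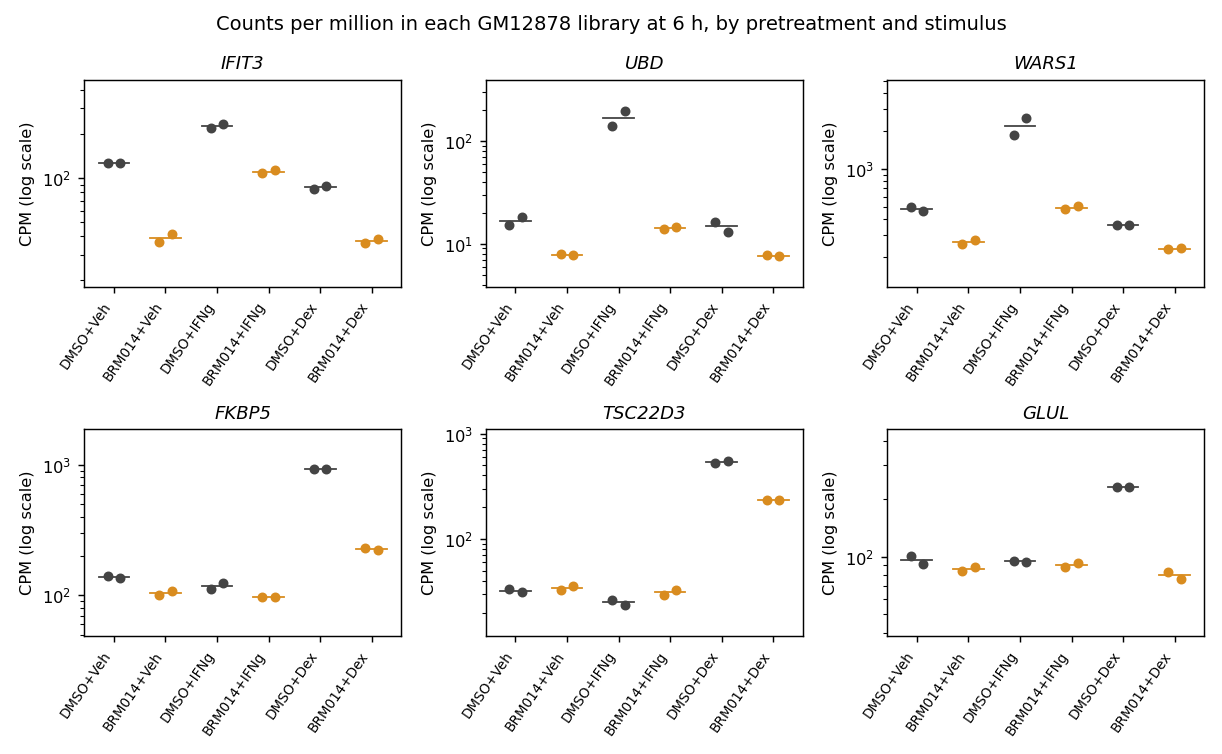
CPM (log scale) of IFIT3, UBD, WARS1, FKBP5, TSC22D3 and GLUL in each GM12878 library at 6 h, by pretreatment and stimulus; points are libraries and lines are means of 2. IFIT3 with IFNg is at 228 CPM in DMSO and 110.2 in BRM014, and UBD at 169.8 and 14.3.

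The genes that rose over 2-fold in the panel give a list chosen on other libraries. Of 130 IFNg-raised genes 121 were measured in the pretreatment experiment, with a median fold change at 6 h of 1.19 in DMSO and 0.88 in BRM014. The slope through 0 of the latter on the former was 0.602. The interaction was lower for 8 and higher for 2 of them (29 and 5 adjusted over the list alone). The IFNg effect on them was called for 94 in DMSO and 53 in BRM014, and camera on the interaction gave p = 0.0287 with an estimated correlation. Without IFNg the same genes had a median BRM014 fold change of -0.88, with 70 fallen and 2 risen. TAP1, GBP3 and BCL6, named for a high interaction p, had fold changes of 1.76, 1.68 and 2.54 in DMSO and 1.72, 1.5001 and 2.33 in BRM014. Their interactions of -0.044 ± 0.086, -0.18 ± 0.39 and -0.21 ± 0.67 did not pass. Those of GBP3 and BCL6 are too uncertain to show a kept response. At 1 h the medians were 0.22 and 0.080 (ratio 0.369) and the slope 0.474, with 5 interactions, all lower (12 adjusted over the list alone; p = 0.0054 with an estimated correlation). The 20 measured genes that fell over 2-fold in the panel gave no interaction call for a single gene at 6 h, with median fold changes of -0.31 and 0.022, but as a list a higher interaction (camera, p = 0.0343 with an estimated correlation). Among fixed lists, the interaction at 6 h was lower for 3 (SOCS1, WARS1 and UBD) of 42 IFNg targets (2 up and 14 down adjusted over the list alone; adjusted p = 0.052 with an estimated correlation). It was higher for 2 (IFIT3 and OAS2) of 32 type I interferon-stimulated genes (11 up and 2 down adjusted over the list alone). Camera gave them an adjusted p of 0.052 with an estimated correlation. With IFNg present, both lists were still lower in BRM014 than in DMSO (camera adjusted p = 1.9e-04 for each). Of 42 IFNg targets 39 were lower and 1 higher (median -0.96), and of 32 type I genes 28 were lower and 1 higher (median -0.996). The chemokine gene CXCL9, outside the naming rule here and chosen after its values were seen, was at 62.1 and 224 CPM in the DMSO and IFNg libraries and 3.91 on average in BRM014 and IFNg. Its interaction of -4.00 ± 0.98 did not pass (adjusted p = 0.2).

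The IFNg interaction counts moved with single libraries. The 6 h total of 30 became 15 without DMSO and vehicle replicate 2, and 60 and 163 without DMSO and IFNg replicates 1 and 2. It became 13 without BRM014 and vehicle replicate 1, 10 and 12 without BRM014 and IFNg replicates 1 and 2, and 48 with DESeq2. The balance moved too, with 47 lower and 37 higher responses with no filter, 8 and 3 with only the compared groups in the fit, and 57 and 106 without DMSO and IFNg replicate 2. The 1 h total of 10 became 6 without DMSO and vehicle replicate 1 and 6 without BRM014 and vehicle replicate 1. It was 22 lower and 9 higher with no filter, 24 and 4 with only the compared groups in the fit, and 12 and 1 with an offset on GC content, so higher responses at 1 h are not excluded. UBD and WARS1 lost their interaction calls with only the compared groups in the fit (adjusted p = 0.0717 and 0.304). OAS2 lost its call without replicate 1 of DMSO and vehicle, of BRM014 and vehicle or of BRM014 and IFNg (adjusted p = 0.0746, 0.204 and 0.161). The p of 0.0287 for the raised list became 0.0751 and 0.0541 without DMSO and vehicle replicates 1 and 2, and 0.067 without BRM014 and IFNg replicate 2.

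**Figure D4:**
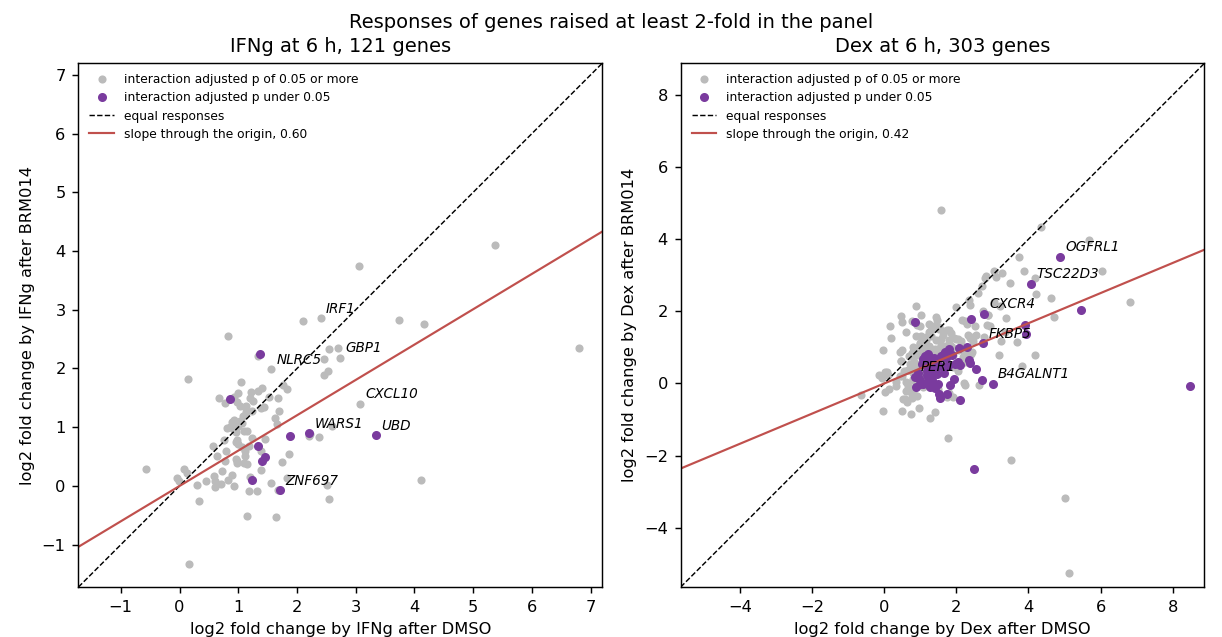
Log2 fold change in BRM014 against that in DMSO at 6 h for the 121 IFNg-raised (left) and 303 Dex-raised genes (right) of the panel; purple points have an interaction adjusted p under 0.05. The fitted lines through 0 have slopes of 0.602 and 0.418.

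The same question was put to Dex. After 1 h in DMSO 55 genes rose and 37 fell, with 2.95 ± 0.067 for TSC22D3, 2.25 ± 0.088 for the chemokine receptor gene CXCR4, 1.94 ± 0.15 for NFIL3 and -1.18 ± 0.065 for TNF. In BRM014 27 rose and 15 fell, with 1.41 ± 0.067, 1.62 ± 0.10 and -1.03 ± 0.064 for TSC22D3, CXCR4 and TNF. At 6 h 1224 rose and 1144 fell in DMSO, and 557 and 622 in BRM014. In both arms 396 rose and 444 fell, and 13 were called in opposite directions. FKBP5 rose by 2.74 ± 0.052 in DMSO and 1.12 ± 0.053 in BRM014, TSC22D3 by 4.07 ± 0.068 and 2.77 ± 0.067, and OGFRL1 by 4.86 ± 0.12 and 3.52 ± 0.12. RASD1, a Ras-related gene, had 2 counts in the DMSO and vehicle libraries at 6 h and was 126-fold higher with Dex (95% counting interval 34.5 to 1049). Glucocorticoid-induced genes rose in 22 and fell in 1 (SGK1) of 33 cases in DMSO (24 up and 1 down adjusted over the list alone; camera adjusted p = 9.54e-08) and rose in 16 in BRM014 (20 up adjusted over the list alone; camera adjusted p = 5.14e-07). NF-kB and inflammatory targets fell in 23 (camera adjusted p = 0.0164) and 15 (adjusted p = 0.0785 with an estimated correlation) of 38 cases, with -1.44 ± 0.062 and -1.12 ± 0.062 for LTA. B cell identity genes fell in 20 (camera adjusted p = 0.0158) and 11 (adjusted p = 0.0785 with an estimated correlation) of 37. The 1 h totals became 61 (from 92, DMSO) without DMSO and Dex 1 h replicate 1, and 27 and 27 (from 42, BRM014) without BRM014 and vehicle 1 h replicate 1 and BRM014 and Dex 1 h replicate 2. At 6 h in BRM014 the total of 1179 became 769 without BRM014 and vehicle 6 h replicate 2, and with only the compared groups in the fit the 1 h total in DMSO was 163.

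The interaction of Dex and BRM014 at 6 h was lower for 261 genes and higher for 158. It was -1.62 ± 0.073 for FKBP5 (adjusted p = 4.73e-16), -1.38 ± 0.086 for GLUL, the glutamine synthetase gene (ENSG00000135821.18, chromosome 1, 182378098 to 182392206), and -1.30 ± 0.095 for TSC22D3. It was -2.04 ± 0.15 for the GTPase gene RHOB and -1.95 ± 0.31 for LHFPL6. FKBP5 stood at 139 ± 3.87 and 925 ± 7.08 CPM (SD, n = 2) in DMSO without and with Dex, and at 104 ± 6.05 and 227 ± 6.47 in BRM014. ACKR3, an atypical chemokine receptor gene, CRYBG1 and LBH had higher interactions, with 1.69 ± 0.21, 1.16 ± 0.10 and 1.15 ± 0.13. NR3C1, lower with Dex in DMSO (-0.64 ± 0.061), had -0.15 ± 0.063 in BRM014, an interaction of 0.49 ± 0.088 (adjusted p = 6.47e-04). Of 341 panel genes raised over 2-fold by Dex 303 were measured, with medians of 1.39 in DMSO and 0.75 in BRM014 and a slope of 0.418. The interaction was lower for 73 and higher for 1 (106 and 4 adjusted over the list alone; camera, p = 1.52e-09 with an estimated correlation). RASSF8 had 2.83 ± 0.67 and 2.97 ± 0.998, the latter not called in edgeR (adjusted p = 0.0686). Its interaction of 0.14 ± 0.83 was not called and is too uncertain to show a kept response. B4GALNT1 had 3.003 ± 0.39 and -0.0091 ± 0.41. Among 161 measured genes lowered over 2-fold in the panel, the medians were -1.03 and -0.63, with 11 higher and 1 lower interactions.

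In the glucocorticoid-induced list the 6 h interaction was lower for 13 and higher for 1, BIRC3 (2 up and 17 down adjusted over the list alone; camera adjusted p = 2.29e-05). It was higher for 5 NF-kB and inflammatory targets, BIRC3, CCL22, LTA, LTB and BCL2A1 (9 up and 1 down adjusted over the list alone; adjusted p = 0.135 with an estimated correlation), with 0.73 ± 0.11 for LTB. It was also higher for 7 B cell identity genes (9 up and 2 down adjusted over the list alone; adjusted p = 0.135 with an estimated correlation), with 0.49 ± 0.081 for CD22. BIRC3 lost its call without any 1 of the 8 libraries (adjusted p from 0.0506 to 0.165) and LTA without 6 of them (all but replicate 2 of either vehicle group; adjusted p from 0.0787 to 0.306). At 1 h 12 genes had lower and 6 higher interactions, with -1.53 ± 0.10 for TSC22D3 and -1.65 ± 0.24 for NFIL3. Of the lower ones 5 (TSC22D3, PER1, KLF9, ZFP36L2 and KLF6) are in the glucocorticoid-induced list (1 up and 8 down adjusted over the list alone; camera adjusted p = 7.99e-05). KLF9 lost its call without any 1 of the 8 libraries (adjusted p from 0.0827 to 0.267). PER1 lost its call without replicate 1 or 2 of DMSO and vehicle, replicate 1 of DMSO and Dex or of BRM014 and vehicle, or replicate 2 of BRM014 and Dex (adjusted p from 0.2 to 0.984). The panel list had medians of 0.12 and 0.048 (ratio 0.401) and a slope of 0.170, which noise can pull towards 0 since only 24 of 303 genes were called in DMSO, with 9 interactions, all lower (13 adjusted over the list alone). The 1 h total of 18 became 10 and 9 without DMSO and vehicle replicates 1 and 2, 8 and 10 without DMSO and Dex replicates 1 and 2 and 9 without BRM014 and vehicle replicate 1. With no filter it was 20 lower and 18 higher. The 6 h total of 419 became 267 without BRM014 and vehicle 6 h replicate 1.

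In HepG2 the question was what 24 h of BRM014 does in a liver cancer line. The inhibitor lowered 3037 genes and raised 2580 of 13349 tested, 1395 and 487 by over 2-fold (n = 2 each). DESeq2 called fewer: among genes tested in both lines it called 1592 falls and 1577 rises in HepG2 (12571 genes), against 2313 and 2396 with edgeR (11920 genes). In simulated HepG2 data, with far fewer changed genes than are called here, 21 of 182 edgeR calls were false. That share depends on how many genes change, so it does not carry over to these calls. FABP1, the liver fatty acid-binding protein gene (ENSG00000163586.9, chromosome 2, 88122982 to 88128062), changed by -6.86 ± 0.19, from 142 ± 10.7 to 0.966 ± 0.479 CPM (SD, n = 2). The thyroid hormone carrier gene TTR changed by -4.60 ± 0.13, the apolipoprotein gene APOM by -3.49 ± 0.11, G6PC1, the last enzyme of glucose release, by -8.22 ± 0.29, and DEPP1 by -8.09 ± 0.17. The chemokine receptor gene CCR6 (ENSG00000112486.16, chromosome 6, 167111807 to 167139141) and the bile acid synthesis gene CYP8B1 had 0 counts with BRM014 and were at least 107-fold and 62.2-fold lower against a floor of 3 counts over the group. With 1 to 3 counts left, TUBB1 was 475-fold lower (95% counting interval 162 to 2307), HAL, the histidine ammonia-lyase gene, 242-fold (66.7 to 2005) and ROBO4 195-fold (53.7 to 1618). Such intervals and floors cover counting error only. KCNJ11, a potassium channel gene (ENSG00000187486.5, chromosome 11, 17365172 to 17389331), rose by 4.70 ± 0.49, the semaphorin gene SEMA3C by 4.06 ± 0.37, the homeobox gene DLX2 by 3.98 ± 0.26, the growth factor gene AREG by 3.60 ± 0.17 and the collagen gene COL1A1 by 3.17 ± 0.14. SMARCA4 rose by 0.56 ± 0.087 and SMARCA2 changed by -0.58 ± 0.13 (adjusted p = 5.53e-05 and 0.00137). Without the shallow BRM014 replicate 2, 5590 genes were called in place of 5617.

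Hepatocyte genes fell in 43 and rose in 2 (FGG and FOXA1) of 50 cases (2 up and 43 down adjusted over the list alone; adjusted p = 0.254 with an estimated correlation), with a median of -1.75. In HepG2 camera with an estimated correlation has only 2 degrees of freedom, so its p-values here and in the next paragraph have little power. Drug and bile acid metabolism genes fell in 10 and rose in 2 (CYP1A1 and SLC51B) of 15 (2 up and 10 down adjusted over the list alone; adjusted p = 0.428 with an estimated correlation), with -1.53 ± 0.10 for CYP27A1. CYP3A5, which shares reads with its paralogs and is uncertain, was 74.2-fold lower (20.2 to 618). Cholesterol synthesis genes fell in 17 and rose in 1 (PMVK) of 23 (1 up and 18 down adjusted over the list alone; adjusted p = 0.254 with an estimated correlation), with -1.44 ± 0.15 for EBP and -1.42 ± 0.10 for MSMO1. Immediate-early genes rose in 17 and fell in 4 (JUN, IER3, IER5 and DUSP5) of 26 (17 up and 4 down adjusted over the list alone; adjusted p = 0.254 with an estimated correlation), with 2.55 ± 0.10 for EGR1 and 2.74 ± 0.13 for JUNB. BAF subunit genes rose in 13 and fell in 2 (SMARCA2 and SMARCD2) of 25 (13 up and 2 down adjusted over the list alone; adjusted p = 0.428 with an estimated correlation), with 0.66 ± 0.090 for ARID1A. The call of this list with the preset correlation was lost without DMSO replicate 1 (adjusted p = 0.0524). Of YAP and TEAD targets 5 (CCN1, ANKRD1, AXL, PTPN14 and ASAP1) rose and 7 fell of 18 (5 up and 8 down adjusted over the list alone), with 1.29 ± 0.088 for CCN1 and -1.90 ± 0.17 for NT5E. Of extracellular matrix and adhesion genes 10 rose and 10 fell of 25 (11 up and 11 down adjusted over the list alone), with 2.66 ± 0.092 for the tight junction gene CLDN1 and -1.30 ± 0.087 for TGFBI. Of p53 targets 9 rose and 5 (TP53INP1, PLK2, TNFRSF10B, PHLDA3 and SPATA18) fell of 34 (9 up and 5 down adjusted over the list alone). Of NF-kB and inflammatory targets 5 (BIRC3, RELB, REL, NFKB1 and ICAM1) rose and 6 fell of 25 (5 up and 6 down adjusted over the list alone), with -2.66 ± 0.13 for the chemokine gene CCL20.

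Glucocorticoid-induced genes in HepG2 gave 16 rises and 7 falls of 31 (16 up and 9 down adjusted over the list alone), with -1.72 ± 0.089 for GLUL. Type I interferon-stimulated genes fell in 8 of 17 (9 down adjusted over the list alone), with -3.03 ± 0.32 for OAS1. Cell cycle genes were lower in part: 9 fell and 2 (RRM2 and CCNE2) rose of 22 S phase genes (2 up and 9 down adjusted over the list alone), with 2.18 ± 0.088 for RRM2 and -0.77 ± 0.089 for MCM3. Of 26 G2 and M phase genes 13 fell (13 down adjusted over the list alone), with -0.95 ± 0.11 for CCNB2. Heat shock genes rose in 7 and fell in 1 (HSPB1) of 16 (7 up and 1 down adjusted over the list alone; adjusted p = 0.428 with an estimated correlation), with 1.25 ± 0.088 for HSPA8. Stress and unfolded protein response genes rose in 7 and fell in 6 of 23 (7 up and 6 down adjusted over the list alone). Histone genes are uncertain here too, as near-identical copies in libraries enriched for polyadenylated RNA. Of 6 histone genes H2AC6 rose (0.43 ± 0.16), a call lost without DMSO replicate 1, DMSO replicate 2 or BRM014 replicate 2 (adjusted p = 0.112, 0.11 and 0.152). Mitochondrially encoded transcripts fell in 6 of 13 (7 down adjusted over the list alone), with -0.60 ± 0.12 for MT-CO3. These copies are uncertain because nuclear pseudogenes share their sequence. MT transcripts made up 6.06% and 4.66% of the counts in the DMSO libraries and 4.01% and 4.52% in the BRM014 libraries. Of markers of other cell types, all 4 measured myeloid genes, LYZ, CSF3R, AIF1 and CD14, fell (4 down adjusted over the list alone; adjusted p = 0.428 with an estimated correlation), with -1.28 ± 0.084 for LYZ and -3.29 ± 0.27 for CSF3R. Also, 2 of 3 T and NK cell genes, CD4 and CD7, fell (2 down adjusted over the list alone). Without BRM014 replicate 1 the calls of AIF1, CD14, CD4 and CD7 were lost (adjusted p = 0.0943, 0.487, 0.0501 and 0.502), as were those of CD14 and CD7 without DMSO replicate 1 (adjusted p = 0.0975 and 0.124) and of CD14 without DMSO replicate 2 (adjusted p = 0.239).

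Cell line and time both differ between the BRM014 experiments, and their calls were set side by side without a test of the difference. Among 11920 genes tested in both, 771 rose and 767 fell in both GM12878 at 6 h and HepG2 at 24 h, where independent lists would share 523 and 418 (Fisher's exact test, p = 3.17e-40 and 1.46e-87), and 638 went in opposite directions against 938. Fisher's test takes genes as independent, which they are not, and the expected numbers were not matched on expression. Pearson's r across the genes called in either, which are not independent replicates, was 0.34. SMARCA4 rose and SMARCA2 fell in both lines, DEPP1 had -3.88 ± 0.27 and -8.09 ± 0.17, OAS1 -2.14 ± 0.079 and -3.03 ± 0.32, and BICRAL 0.75 ± 0.083 and 0.85 ± 0.13. The number called in the same direction, 1538, was 939 with DESeq2 and 179 for changes of at least 2-fold.

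Camera p-values were given for lists called with the preset correlation of 0.01. Of 175 list tests 93 were called with the preset correlation and 44 of these held with an estimated one. They were NF-kB and IFNg targets with TNF, the 4 lists tested with LPS, the 3 tested with IL2, all lists but MHC class II and G2 and M phase genes with IFNg in the panel, and glucocorticoid, NF-kB, IFNg target, MHC class II and B cell genes with Dex in the panel. In the pretreatment experiment they were IFNg targets in both arms and times, type I interferon and MHC class I genes in both arms at 6 h, B cell genes with IFNg in DMSO at 6 h, glucocorticoid-induced genes in both arms and times, and NF-kB and B cell genes with Dex in DMSO at 6 h. For BRM014 alone they were NF-kB and B cell genes at both times and IFNg, type I interferon and immediate-early genes at 6 h. For the interactions they were IFNg targets at 1 h with IFNg and glucocorticoid-induced genes at both times with Dex. No call for the IFNg interaction at 6 h held. None held in HepG2 either, but there camera with an estimated correlation has only 2 degrees of freedom. It could hardly call a list in HepG2, so this does not weigh against those lists. Median, mean and the direction of camera or fry differed in sign in 25 tests, of which 3 were called with the preset correlation, always as higher: NF-kB and inflammatory targets with IFNg at 1 h in DMSO (median and mean -0.014 and 0.029) and at 6 h in BRM014 (0.035 and -0.0068), and plasma cell genes with Dex at 1 h in BRM014 (-0.019 and 0.064). Lists given above whose signs also differed were B cell genes with TNF, glucocorticoid-induced genes with BRM014 at 1 h, cholesterol synthesis and mitochondrially encoded genes with BRM014 at 6 h, and YAP and TEAD, NF-kB and stress response genes in HepG2.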

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

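The tests of GC content, of scaling for the Dex pattern and of NR3C1 were chosen only after the result was seen, and the other tests were written before, once totals with a library left out or other size factors were known. Effects that differed between 1 h and 6 h, by an edgeR test of the difference between the times, were those of IFNg in DMSO for 305 genes, of Dex in DMSO for 1181 and of BRM014 without a stimulus for 2844. Genes called at both times had the same direction in 49 of 49 cases for IFNg, 83 of 83 for Dex and 269 of 276 for BRM014. The other 7, named after their values were seen, had these fold changes at 1 h and 6 h: CD69 (0.68 and -0.38), DSE (-0.27 and 0.24), EGR1 (0.74 and -0.38), DUSP4 (0.44 and -0.62), DUSP5 (0.42 and -0.43), PNRC1 (0.27 and -0.20) and BTG2 (0.30 and -0.41) (adjusted p of the difference from 4.54e-10 to 0.00121).

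The panel vehicles differed in 69 genes, whose median signed fold change was 0.28 over both PBS libraries, 0.32 against replicate 1 and 0.26 against replicate 2, but these libraries also chose the genes, so the test says nothing of PBS replicate 1 alone. Of 196 genes called from the replicate 1 libraries, 140 (71.4%, 95% interval 64.6 to 77.6%; all genes 53.5%) had the same sign in the replicate 2 libraries, over the 65% set beforehand against a single library although the interval is not, and their median was 0.065 there against 0.36. Fold changes between the vehicles followed GC content, with a Spearman's rho of -0.48 across 9692 genes. For single libraries rho was 0.62 and -0.054 for PBS replicates 1 and 2 and -0.31 and -0.11 for DMSO replicates 1 and 2. Yet 47 of the 69 genes passed with a GC offset, which argues against that trend as the whole cause. The test with 196 genes set the replicate 1 libraries of both vehicles against each other, so it cannot say which of them carries a difference. Its interval takes genes as independent, which they are not. A shared effect of the solvent and a difference carried mostly by PBS replicate 1 or by DMSO replicate 1 cannot be told apart with 2 libraries per vehicle. The comparison of DMSO with PBS is itself a test of the solvent, with 69 calls, 13 without PBS replicate 1 (12 of them among the 69) and SLC30A1 called under each library left out, but it does not separate the solvent from other differences between these libraries.

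Dex raised its panel genes less under BRM014, and the genes may already have been shifted by the inhibitor. Among 91 raised genes with a BRM014 fold change under 0.25 in size in the IFNg libraries the slope was 0.54 (95% interval 0.46 to 0.62 over 2000 resamples of genes), short of the 0.8 that explanation needs, but the interval crosses the bound of 0.6 set against it, so it is not excluded. The mean interaction was -0.87 for raised and 0.37 for lowered genes, and opposite signs argue against a common scaling error. NR3C1, which encodes the receptor, had -0.59 ± 0.061 under BRM014 at 6 h (adjusted p = 3.24e-09 in edgeR), which would fit a weaker receptor signal, but -0.059 ± 0.061 at 1 h (adjusted p = 0.9), when the raised genes already had lower interactions (camera p = 1.93e-04 with an estimated correlation), which argues against less receptor transcript as the cause at 1 h. Receptor protein and binding were not analysed here, so a lower receptor at 6 h and a direct need for BAF at the Dex genes stay open.

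Falls over 2-fold outnumbered rises 3.35 to 1 in GM12878 and 2.86 to 1 in HepG2. Without the shallow HepG2 library the ratio was 2.74 (1507 and 550 genes), and among genes of at least 30 CPM it was at least 2.93 (192 and 7 in GM12878, 416 and 142 in HepG2), which argues against depth and the detection limit. With other size factors it was at least 2.80, but they moved no library by over 0.0168 on the log2 scale, so although the ratio lies over the 1.5 set beforehand this was taken, once seen, as a test that cannot tell. A common shift of 0.31 in GM12878 or 0.34 in HepG2 would balance falls and rises, and spike-in identifiers hold 0 counts. A change in total mRNA per cell, which would make these ratios relative, therefore stays open beside a loss of BAF-dependent transcription.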

How the results depend on the processing

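The GC content offset and the crossed block were tests chosen only after the data were seen. Over all settings 5938 of 6401 values of named genes kept direction and side of the threshold, 463 lost their call and none turned, and with 1 library left out 361 of 2779 lost it. Of 1974 list values 1880 stayed, 37 lost and 43 gained a call and 14 turned, Dox aside. Leaving out a library of a pair leaves 1, which is assumed to vary like the other groups. Scaling moved no library by over 0.0168 on the log2 scale. The calls of BRM014 at 6 h, Dex at 6 h in DMSO and HepG2 stayed within 1.5 times in every setting. With 2 libraries per group, and 3.06 M counts in the shallowest, small changes and weakly expressed genes are missed. For every changed value given here the cause was not tested, except that fewer libraries and groups give fewer degrees of freedom.

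With no filter the calls were 22 for TNF, 20 for LPS, 73 for IL2, 132 between vehicles, 27 for IFNg and 64 for Dex at 1 h in BRM014, 31 and 84 for the IFNg interactions at 1 h and 6 h and 38 for the Dex interaction at 1 h. With DESeq2 they were 1226 for panel IFNg, 2649 for panel Dex and 48 for the IFNg interaction at 6 h. With only the compared groups they were 2 for LPS, 11 between vehicles, 128 and 349 for IFNg in DMSO at 1 h and 6 h, 470 for IFNg in BRM014 at 6 h, 163 for Dex in DMSO at 1 h, and 28 and 11 for the IFNg interactions. With the GC offset they were 16 for TNF, 1 for LPS and 67 for IL2. Against DMSO alone they were 38, 35 and 98 for TNF, LPS and IL2, and against PBS alone 0 in edgeR for TNF and 10 for IL2. The retained slope was 0.528 for IFNg with a list from the DMSO arm, which the same libraries chose, and 0.524 for Dex with the 50 largest responses. Genes called in the same direction in GM12878 and HepG2 were 939 with DESeq2 and 179 at 2-fold or more. The Dox p53 median was 1.16 against DMSO alone.

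The replicate block gave 5 calls for TNF and 16 for LPS and moved no other total by over 1.5 times. Differences between replicates 1 and 2 correlated across genes between groups at -0.16 to 0.44 in the panel (10 of 21 pairs over 0.1) and -0.38 to 0.45 in pretreatment (25 of 66), so the numbers do not pair the samples. In HepG2 the correlation was -0.42, and the replicate block gave 4749 calls and the crossed block 6859.

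With 1 library left out the lowest and highest totals were 0 to 8 for TNF, 0 to 5 for LPS, 11 to 56 for IL2, 1060 to 2024 for panel IFNg and 2 to 410 between vehicles. For IFNg they were 50 to 59 and 663 to 992 in DMSO at 1 h and 6 h, 10 to 14 and 170 to 211 in BRM014, and 6 to 9 and 10 to 163 for the interactions. For Dex they were 61 to 74 in DMSO at 1 h, 27 to 33 and 769 to 829 in BRM014 at 1 h and 6 h, and 8 to 15 and 267 to 375 for the interactions. BRM014 at 1 h gave 149 to 203. The retained slopes ran from 0.494 to 0.679 for IFNg and 0.316 to 0.463 for Dex.

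List medians that turned were those of B cell genes with TNF against DMSO alone (0.036) and with LPS against PBS alone (-0.0030), and of histones with Dox against DMSO alone (0.018). The others turned with 1 library left out, and their lowest and highest medians follow with the library at the turned end. In DMSO at 1 h these were -0.035 to 0.022 for NF-kB genes with IFNg and -0.042 to 0.051 for plasma cell genes with Dex (both DMSO and vehicle replicate 2), and -0.15 to 0.0074 for the type I list in the IFNg interaction (DMSO and IFNg replicate 1). In BRM014 at 1 h they were -0.0049 to 0.074 for MHC class I genes with IFNg (BRM014 and IFNg replicate 1). With Dex they were -0.014 to 0.087 for MHC class II genes (BRM014 and vehicle replicate 1) and -0.051 to 0.032 for plasma cell genes (the same library; 0.024 without BRM014 and Dex replicate 2). At 6 h they were -0.0017 to 0.094 for MHC class II genes with IFNg in DMSO and -0.060 to 0.069 in the Dex interaction (both DMSO and vehicle replicate 2). In BRM014 they were -0.0023 to 0.10 for NF-kB genes with IFNg (BRM014 and vehicle replicate 1) and -0.069 to 0.091 for plasma cell genes with Dex (BRM014 and vehicle replicate 2; -0.0035 without BRM014 and Dex replicate 1).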

Other observations

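The test of zinc finger genes in HepG2 was chosen only after the result in GM12878 was seen. Genes whose symbol starts with ZNF, mostly DNA-binding zinc finger proteins, were higher under BRM014 in GM12878 at 6 h: 160 rose and 32 fell of 494, and 75.5% had a positive fold change against 50.0% of other genes. The hypothesis that this group rises with BAF inhibition was tested in the IFNg libraries, where the pattern had not been sought, and 76.9% were positive (95% interval 73.0 to 80.6%), above the 60% set before. The interval takes genes as independent, which they are not, and the libraries come from the same experiment with the same inhibitor. With Dex the share was 76.3%. In HepG2 it was 52.8% of 451 (95% interval 48.0 to 57.5%), under the 55% set against the hypothesis, but the interval passes it and the hypothesis stays open there.

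Genes lowered by Dex or by IFNg in the panel were often also lowered by BRM014 at 6 h, in libraries that are not shared. Over all genes 951 fell with Dex and BRM014, where independent lists would share 402, and 410 with IFNg and BRM014 against 151, so the shared falls are not particular to Dex. Genes called in opposite directions by IFNg and BRM014 were also more than independent lists would share, 629 against 363, and those that rose in both fewer, 122 against 206. For Dex the excess was set against expression level and the fixed lists, which was not done for IFNg. Within 10 bins of expression the 951 genes were 1.83 times the 519 of independent lists, and without members of the interferon, NF-kB and B cell lists 865, 1.82 times the 474. Genes that rose with both Dex and BRM014 numbered 399 against 410.3, a ratio of 0.972. The hypothesis that expression level accounts for the falls shared with Dex is therefore not borne out. The members of those lists do not account for them either, as 865 remain. They are too few beside 951 genes for that check to have come out otherwise. It therefore says nothing of wider interferon, NF-kB or B cell programmes, and the cause stays open.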
